A study of Mus musculus with 6 samples.

How the data were processed

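Single olfactory sensory neurons, 6 in number, from 6-week-old C57BL/6 mice were each sequenced as its own CEL-Seq2 library on an Illumina NovaSeq instrument, per the labels' protocols. CEL-Seq2 primes RNA at the poly(A) tail, marks each molecule with a unique molecular identifier and amplifies by in vitro transcription, so reads come mainly from the 3' ends of transcripts. Per the labels, the barcode and molecular identifier in read 1 were moved to the read names and only read 2 was aligned. The submitters' processing notes name CASAVA, Bowtie2 2.3.4 and HTSeq and the mouse build mm10, without giving their roles or order. The annotation, the strand setting of the counting, the treatment of reads with several alignments and whether reads with the same molecular identifier were collapsed are not given in the sources used here.

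The deposited values are raw counts per gene symbol, with 55341 genes in 6 columns, 1 column per cell. No column was left unused. Column totals differed between cells and every value was a whole number, so the counts were used as the authors deposited them. A count may therefore stand for a molecule or for a read. All intervals cover counting error only, and they are too narrow if counts are reads amplified from the same molecule.

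All 55341 symbols were found in the GENCODE M21 annotation of GRCm38, the assembly that mm10 names, and gene positions, gene types and exons were taken from it. Positions are 1-based. Without a stated strand setting, reads of a gene and of an overlapping or antisense partner cannot be told apart, and genes with near-identical copies may exchange reads. This concerns the receptor genes Olfr740 to Olfr743, Olfr1372-ps1 with Olfr1383, Hba-a1 with Hba-a2, Bpifb9a with Bpifb9b, the Obp1a and Obp1b family on chromosome X, Obp2a with Obp2b, and the mitochondrial genes with their nuclear copies. Values of these genes are uncertain for that reason.

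CPM values, counts scaled to a common library total, were computed over all genes of a cell. Counts and CPM are given with exact 95% Poisson intervals, and shares with exact 95% Clopper-Pearson intervals. For a gene without counts, the level that 3 counts would give is used as the limit of detection. The labels name no animals, and each library is 1 cell, so the 6 cells form 1 group without biological replicates. Each cell is reported on its own, with the median and range over cells, and no p-value between cells is given. Intervals of ratios and Dixon's limit for a value far from the others describe these libraries only.

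Odorant receptor genes were the 1405 genes named Olfr and the 16 named Taar. A cell was called dominated by 1 receptor when that gene had at least 10 counts and at least 90% of the cell's receptor counts. A total of 23 gene lists with 204 genes covered neuronal functions, cell states and other cell types of the nose. For each list and cell the counts were summed. For the 12 lists with at least 5 members at a mean of at least 10 CPM, the median log2 ratio of a cell to the mean of the other 5 cells was computed with a pseudocount of 10 CPM and placed among 10000 random lists of the same size, drawn from genes of similar mean expression. This percentile describes these libraries and is not a test. Similarity between cells was measured by Spearman's rho across genes with a mean of at least 10 CPM. No column repeats another, since all 6 totals differ.

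The genes named in the text follow a rule. It takes, per cell, the receptor with the most counts and up to 2 further receptors with at least 3 counts. Per list it takes the 4 members with the highest median CPM, and for signal transduction also each member at 0 in any cell. It adds the 10 genes with the highest median CPM outside mitochondrial, ribosomal protein and receptor genes. Per cell it adds the 3 other genes with at least 10 counts and the largest ratio to the next highest cell, a cell at 0 being set to 3 counts. It ends with the 10 genes of highest coefficient of variation among those with a mean of at least 200 CPM and counts in at least 3 cells. List members without a count in the median cell are described mainly through the count of members detected. Some genes that the rule takes are not reported here. Other genes that are named were chosen after their values were seen, and the text says so. The lists, the rule, the measures and most alternatives were fixed before the data were examined.

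The alternatives were detection at 3 or 10 counts, thinning of every cell to the total of the shallowest cell (20 random draws), receptor shares of 50% and 99%, receptor pseudogenes left out, 4 other scalings, pseudocounts of 1 and 50 CPM, no filter on low values, Pearson's r, and each cell left out in turn. Added after the data were seen were receptor genes with at least 3 counts only, Olfr741 and Olfr742 summed, cells under 20000 counts left out, and cell 3 left out of the pooled levels behind the transduction genes without a count.

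The list percentile was tested on simulated data. Counts were drawn for 55341 genes from the means and totals of the 6 cells, with 200 genes changed 4-fold in 1 cell. All 120 simulated lists of 10 changed genes lay above percentile 99, and 1 of 120 lists of unchanged genes lay outside percentiles 1 to 99. These draws hold counting noise only. With each gene also given its excess variation over the 6 cells, a simulation added after the data were seen, the figures were 112 of 120 and 4 of 120. Genes varied independently there, and lists whose members vary together can lie outside more often. In both simulations the list genes were drawn above a higher mean level than the 10 CPM required of real list members. The figures therefore do not cover lists of low or sparse genes. The computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.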

Results

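RNA was profiled in 6 single olfactory sensory neurons, the odour-detecting neurons of the nasal epithelium, from 6-week-old C57BL/6 mice. Each neuron had been recorded from physiologically before it was frozen, and each gave 1 CEL-Seq2 library, here called cells 1 to 6. The labels place all cells in 1 group and name neither the animals nor the recorded responses. How many mice the cells came from is therefore unknown, the differences between cells have no replicate check, and each cell is described with its counting error. Cells 1 to 6 had totals of 8613, 34478, 122546, 60902, 22525 and 11725 counts. A single count was worth 116 CPM in cell 1 and 8.16 CPM in cell 3, so a gene of low expression was far easier to detect in cell 3. Genes with at least 1 count numbered 3058, 7728, 11670, 9584, 6382 and 2855, with a median of 7055. At an equal depth of 8613 counts, cells 1 to 5 had between 3058 and 4010 genes and cell 6 had 2470. Protein-coding genes took 72.8% to 81.5% of the counts. Mitochondrial transcripts took 14.4%, 11.7%, 6.47%, 4.40%, 7.62% and 12.3% in cells 1 to 6. Pseudogenes that are nuclear copies of mitochondrial sequence took a further 7.02%, 4.35%, 3.69%, 1.87%, 3.83% and 7.26%.

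Each of the 6 neurons had 1 odorant receptor gene far above all others, and the 3 receptors found this way, Olfr740, Olfr741 and Olfr743, are neighbours in a single gene cluster. Olfr740 led in cells 1 and 2, Olfr741 in cells 3 and 4, and Olfr743 in cells 5 and 6. The leading receptor held 55.3% to 82.7% of a cell's receptor counts and was between the 16th and the 28th most abundant of all genes. These genes encode G protein-coupled receptors that bind odorants, and a mature olfactory neuron is known to express mainly a single receptor gene. The comparison answers which receptor each recorded neuron carried.

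Olfr740 had 55 of 72 receptor counts in cell 1 (76.4%, 95% Clopper-Pearson interval 64.9% to 85.6%) and 174 of 302 in cell 2 (57.6%, 51.8% to 63.3%). Olfr741 had 425 of 745 in cell 3 (57.0%, 53.4% to 60.6%) and 193 of 349 in cell 4 (55.3%, 49.9% to 60.6%). Olfr743 had 111 of 147 in cell 5 (75.5%, 67.7% to 82.2%) and 43 of 52 in cell 6 (82.7%, 69.7% to 91.8%). Their levels were 6386 CPM (95% Poisson interval 4811 to 8312) and 5047 CPM (4325 to 5855) for Olfr740, 3468 CPM (3146 to 3814) and 3169 CPM (2738 to 3649) for Olfr741, and 4928 CPM (4054 to 5934) and 3667 CPM (2654 to 4940) for Olfr743. The separation between the 3 genes was sharp. Olfr740 had at most 2 counts in cells 3 to 6, Olfr743 at most 2 in cells 1 to 4, and Olfr741 2 counts in cell 1 and 0 in cells 2, 5 and 6.

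The 3 genes lie on the plus strand of chromosome 14 in GRCm38, with Olfr740 at 50445545 to 50456933, Olfr741 at 50472738 to 50488338 and Olfr743 at 50521839 to 50534955. Each is annotated as protein coding, Olfr740 with 2 exons and the other genes with 3. Olfr742, at 50503600 to 50517145, lies between Olfr741 and Olfr743, and the 4 genes span 89411 bases. Olfr742 was counted 48 times in cell 3 (392 CPM) and 16 times in cell 4 (263 CPM), 2 times in cell 1, 1 time in cell 2 and not at all in cells 5 and 6. It shares stretches of identical sequence with its neighbours, so its counts are uncertain. The receptor genes on either side had almost no counts: Olfr738 had 1 in cell 1, Olfr739 had 1 each in cells 2, 3 and 4, and Olfr744 had 0 in each cell.

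No cell reached the limit of 90% set for dominance by 1 receptor, while 6 of 6 reached 50%. The remaining receptor counts were spread thinly, with 15, 80, 85, 73, 24 and 9 receptor genes having a count in cells 1 to 6 and 205 in any cell. Most of these genes had 1 or 2 counts. When receptor genes with at least 3 counts alone were considered, a choice made after the data were seen, the leading share was 100% in cells 1 and 6 and 86.7% in cell 5, against 77.0%, 64.1% and 69.7% in cells 2, 3 and 4. These shares depend on depth, since 3 counts are 348 and 256 CPM in cells 1 and 6 but 24.5 CPM in cell 3, and a single receptor passed in each of cells 1 and 6. The largest second receptor was Olfr1372-ps1 in cell 3, an annotated pseudogene on chromosome 11 (52154722 to 52168159) with 76 counts, 10.2% of that cell's receptor counts. Of the 50-base windows in the last 1000 bases of its transcripts, 23.8% occur in Olfr1383, a gene named after its value was seen, which had 46 counts in cell 3 and 1 in cell 4, so the counts of both are uncertain. Olfr482 had 18 counts in cell 4 and 13 in cell 3. In cell 2, Olfr729 had 8 counts and Olfr981 had 7, and in cell 5 Olfr169 and Olfr281 had 4 counts each. Trace amine-associated receptors, the 16 Taar genes, had 1 count over all cells.

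**Figure D1:**
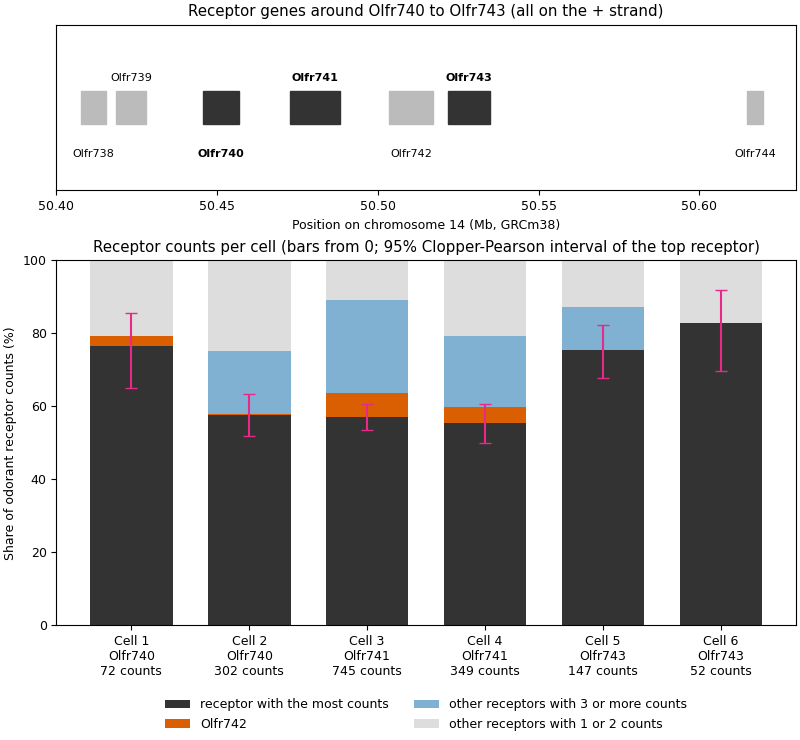
The upper panel maps the receptor genes of chromosome 14 around Olfr740 to Olfr743 (x axis, position in Mb), with the 3 leading receptors in black. The lower panel shows, for each cell, the share of odorant receptor counts (y axis, %) of the leading receptor, of Olfr742 and of other receptors, with 95% Clopper-Pearson intervals for the leading receptor, which held 55.3% to 82.7%.

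Summed over their lists, the transcripts of odour detection and of mature olfactory neurons were abundant in all 6 cells, though single transduction genes were not. The transduction list, which holds the pathway from the G protein to the cilia channels, had a median of 13365 CPM, with 14 of 14 genes found in at least 1 cell and 8 in all cells. In cell 6, 8 of the 14 genes had a count, and Stoml3 gave 6738 of the list's 12537 CPM. The list of other mature neuron markers had a median of 15825 CPM (13185 to 22636), with 9 of 9 genes found and 7 in all cells. The most abundant members were Stoml3, a membrane protein of the olfactory cilia (median 5733 CPM, 3996 to 12539), and Omp, the olfactory marker protein (6161 CPM, 4680 to 9441). Gfy, which encodes the Golgi protein goofy, had a median of 3797 CPM, and Ncam1 and Uchl1 had 1859 and 1138 CPM.

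The G protein subunits Gnal and Gng13 were even across cells. Gnal, the olfactory G protein alpha subunit, ran from 1276 to 2131 CPM, and Gng13, its gamma subunit partner, from 1465 to 2204 CPM. Gnb1, the beta subunit, lay between 1836 and 2786 CPM in cells 1 to 5 and at 768 CPM (9 counts, 351 to 1457) in cell 6. Summed over the transduction list, cell 1 was highest with 25775 CPM (22496 to 29398) and cell 4 lowest with 12199.9 CPM (11338 to 13109.6). The median member was 0.95 log2 units above the other cells in cell 1, at percentile 99.8 of matched random lists, and Stoml3 gave 12539 of the 25775 CPM. Cell 1 was the shallowest library (8613 counts), with the highest share of mitochondrial counts (14.4%) and, after cell 2, the highest sum of gland and secretory markers (6850.1 CPM).

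Cell 6 lacked counts for 5 transduction genes together: the channel subunits Cnga2, Cnga4 and Cngb1, the chloride channel Ano2 and the phosphodiesterase Pde1c. At the pooled rate of the other 5 cells, 6.59, 3.81, 2.07, 3.62 and 7.30 counts of these genes would fall in a cell of its depth. Cell 3 carries that rate, and without it 4.63, 1.11, 0.649, 1.85 and 3.89 counts would fall there, a step taken after the data were seen. A count of 0 in cell 6 allows up to 256 CPM at 3 counts and 315 CPM at the exact Poisson bound. The pooled level of the other cells was 562 CPM for Cnga2 (395 CPM without cell 3) and 622 CPM for Pde1c (332 CPM). Single cells lay under the Poisson bound, with Cnga2 at 296 CPM in cell 4 and Pde1c at 203 CPM in cell 2. Without cell 3 the pooled levels of Cnga4, Cngb1 and Ano2 were 94.8, 55.3 and 158 CPM, so lower levels of these 3 genes were not detectable in cell 6. These limits hold for each gene alone, and the 5 genes were not tested as a set. In cell 6 the transduction list as a whole lay at percentile 1.44 of matched random lists, its lowest among the 6 cells.

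Some transduction genes had few counts in cell 4, a deeper library, although the list as a whole lay inside the range of random lists there (percentile 6.10). Cell 4 had 2 counts of Cnga4 (32.8 CPM) and 1 of Cngb1 (16.4 CPM), against 69 (563 CPM) and 37 (302 CPM) in cell 3, the highest cell. The ratios of cell 3 to cell 4 were 17.1 (95% interval 4.57 to 144) and 18.4 (3.10 to 746). For Adcy3, the adenylyl cyclase of the pathway, named after its values were seen, the counts were 152 and 5 and the ratio was 15.1 (6.33 to 47.2). Ano2, Pde1c, Cnga2 and Stoml3 were also higher in cell 3, with ratios of 4.72 (2.04 to 13.4), 2.81 (1.74 to 4.77), 2.48 (1.49 to 4.38) and 1.82 (1.60 to 2.09). So was Ric8b, named after its values were seen, with 2.71 (1.84 to 4.11). Gnal was level with a ratio of 1.13 (0.879 to 1.46), as were Gnb1 with 0.874 and Gng13 with 0.911. Pde4a and Slc12a2, named after their values were seen, were level too, with 1.11 and 0.994. These ratios compare cell 4 with cell 3 alone. In cell 4, Stoml3 (4729 CPM) lay above cells 2 and 5 (4525 and 3996 CPM), and Pde1c (328 CPM) above cell 2 (203 CPM). Cnga2 and Ano2 (296 and 98.5 CPM) lay not far below cell 2 (348 and 116 CPM). Other mature markers also differed: Omp and Gfy were higher in cell 3 (ratios 2.02 and 1.77), Uchl1 and Ncam1 lower (0.688 and 0.637). Cell 4 had the highest sum of red blood cell markers (12610.4 CPM). Cell 5 had 1 count each of Cnga4 and Cngb1 (44.4 CPM). Slc24a4, the sodium-calcium exchanger, had 1 count in cell 1, 2 in cell 3 and 0 in the other 4 cells, where fewer than 1 count was due at the pooled rate, so its absence there was not detectable at this depth.

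Genes that follow neuronal activity and guide axons differed widely between cells. The axon guidance and activity list (12 of 13 genes found) had a median of 12476 CPM and ran from 6190.3 CPM (5581 to 6848) in cell 4 to 16582 CPM (15868 to 17318.5) in cell 3. Kirrel2, an adhesion molecule whose expression follows activity, had 302 counts in cell 3 (2464 CPM) and 5 in cell 4 (82.1 CPM), the highest and the lowest of the 6 cells. The ratio was 30.0 (95% interval 12.7 to 93.1). Pcp4l1 ran from 171 CPM (2 counts) in cell 6 and 575 CPM in cell 4 to 4333 CPM in cell 3. S100a5, a calcium-binding protein of active olfactory neurons, stayed between 4992 and 9126 CPM, and Sema7a between 171 and 697 CPM. In cell 4 the median member of the list lay 1.88 log2 units below the other cells (log2 ratio -1.88, percentile 0.030). Cell 4 also had the highest sum of red blood cell markers (12610.4 CPM) and, after cell 2, the highest of sustentacular cell markers (887 CPM).

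Markers of immature neurons were far lower than those of mature neurons and were uneven between cells. The list (8 of 10 genes found) had a median of 2011 CPM, from 813 CPM in cell 1 to 3300.4 CPM in cell 4. Stmn2 had the highest median of its members, 834 CPM. Gap43, a growth-associated protein of extending axons, had 8 counts in cell 6 (682 CPM), 13 in cell 4 (213 CPM), 1 in cell 3 (8.16 CPM) and 0 in cell 1. Stmn1 had 34 counts in cell 4 (558 CPM) and 10 in cell 6 (853 CPM), against 5 in cell 3 (40.8 CPM) and 0 in cell 1. Marcksl1 had 19 counts in cell 4 and 0 in cell 3. The median log2 ratio of the list was -3.04 in cell 3 (below all 10000 random lists; -1.77 with a pseudocount of 50 CPM) and 1.04 in cell 4 (percentile 99.2).

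The machinery of receptor choice, synapse and excitability was present at moderate levels. The receptor choice and trafficking list had a median of 3695 CPM (2670.4 to 4479.9), with 13 of 13 genes found and 5 in all cells. Its leading member was the transcription factor Atf5, with a median of 1231 CPM (813 to 2167). The transcription factors Ebf2, Ebf3 and Ebf1 followed at 783, 352 and 341 CPM. Presynaptic genes had a median of 2611 CPM (2322 to 3134), with 10 of 10 found. Syt1 led with 550 CPM, running from 49.3 CPM (3 counts) in cell 4 to 813 CPM in cell 1, followed by Snap25 (360 CPM) and Vamp2 (307 CPM).

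Voltage-gated channels had a median of 2429 CPM (1624 to 3215), with 10 of 12 genes found. The potassium channel Kcnc4 had a median of 670.5 CPM and the sodium channel Scn9a of 355 CPM, ahead of the T-type calcium channel Cacna1h (174 CPM). The channel list lay at percentile 99.3 in cell 3, with a median log2 ratio of 0.64, and at 98.9 with a pseudocount of 50 CPM. Ciliary transport genes were low, with a median of 702 CPM (341 to 1691) and 12 of 12 found. Kif3a, a motor subunit of intraflagellar transport, had 45 counts in cell 4 (739 CPM), and Bbs2, Ift20 and Cetn2 had medians of 116, 87.0 and 53.6 CPM.

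Counts of zonal markers came mainly from the ventral list. Genes of the ventral zone of the epithelium had a median of 790 CPM (426 to 1509), with 5 of 5 found, while the dorsal list, of 2 genes, had 2 counts in total, of Nqo1 in cell 2, and none of Acsm4. A dorsal count of 0 allows up to 30.1 and 60.6 CPM in cells 3 and 4, but 428, 164 and 315 CPM in cells 1, 5 and 6, where it says little. Among the ventral genes, the transcription factors Nfib, Nfix and Nfia had medians of 323, 195 and 74.3 CPM, and the adhesion molecule Ncam2 had 99.3 CPM. Markers of atypical olfactory neurons were almost absent, with 1 of 6 genes found. Car2 had 5 counts over all cells, and Gucy2d, Gucy1b2 and Trpc2 had none.

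**Figure D2:**
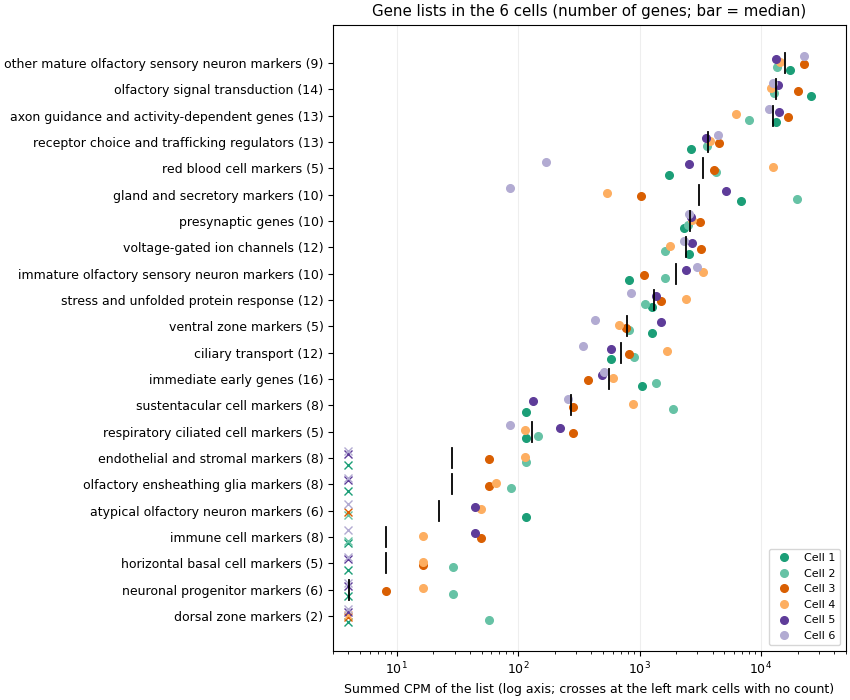
Summed CPM (x axis, log scale) of 22 gene lists in the 6 cells, 1 point per cell and a bar at the median, with crosses at the left edge for cells without a count. The lists of transduction genes and of other mature markers have medians of 13365 and 15825 CPM, while the lists of other cell types are low apart from the red blood cell and the gland and secretory lists.

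Immediate early genes, which respond to stimulation within minutes, were low. The list had a median of 560 CPM (375 to 1363), with 11 of 16 genes found. Dusp1, Jun, Fos and Junb had medians of 177, 176, 53.6 and 8.21 CPM. The sum was highest in cell 2, with 15 counts of Jun (435 CPM) and 7 of Junb (203 CPM), and its median member lay 0.91 log2 units above the other cells (percentile 99.9). The list had 47 counts in cell 2, spread over 9 genes. Jun itself read higher in cell 6 (512 CPM, 6 counts, 188 to 1114), but its interval there overlapped that of cell 2 (244 to 718). Cell 2 also had the highest sums of gland and secretory (19809.7 CPM) and sustentacular cell markers (1885 CPM). Stress and unfolded protein response genes had a median of 1327 CPM (853 to 2397), with 11 of 12 found. Atf4, Hspa5, Hsp90b1 and Calr had medians of 326, 271, 175 and 152 CPM. Ddit3, a transcription factor of the stress response, had 88 counts in cell 4 (1445 CPM, 1159 to 1780.2), 10 in cell 3 (81.6 CPM), 5 in cell 2, 1 in cell 5 and 0 in cells 1 and 6.

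Transcripts known from glands and from red blood cells were found beside the neuronal ones, at levels that differed widely between cells. The gland and secretory list (8 of 10 genes found) had 6850.1, 19809.7, 1028, 542, 5149.8 and 85.3 CPM in cells 1 to 6. The red blood cell list (4 of 5 found) had 1742, 4264, 4080.1, 12610.4, 2575 and 171 CPM. Obp1a and Obp2a, which encode odorant-binding proteins, had 354 and 89 counts in cell 2 (10267 and 2581 CPM) and at most 6 in any other cell. Bpifb9a and Bpifb9b, near-identical secreted proteins of nasal glands, were spread more widely: Bpifb9a had 3599, 3625.5 and 2397 CPM in cells 1, 2 and 5, 465 and 148 CPM in cells 3 and 4, and no count in cell 6. In the gland list the median log2 ratio was 1.45 in cell 2 (percentile 99.97) and -2.06, -3.42 and -6.68 in cells 3, 4 and 6 (each below percentile 1). Without the filter on low values these ratios were 0.61, -1.12, -1.89 and -4.12, still above percentile 99 and below percentile 1. Each cell is compared with the mean of the other 5, so the high levels of cell 2 lower the ratios of cells 3, 4 and 6. These low ratios are therefore not separate from the high one, and ratios without cell 2 in the mean were not computed.

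The hemoglobin genes had their highest level in cell 4, with 218 counts of Hba-a1 (3580 CPM), 211 of Hba-a2 (3465 CPM), 251 of Hbb-bs (4121 CPM) and 88 of Hbb-bt (1445 CPM). Cell 6 had 2 hemoglobin counts in all. Alas2, the heme synthesis enzyme of red cell precursors and the remaining gene of the list, had no count.

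Markers of the other cell types of the epithelium were low. Sustentacular cell genes (5 of 8 found) had a median of 271 CPM (586 CPM without the cells under 20000 counts) and reached 1885 CPM in cell 2, where Cbr2 and Sec14l3 had 21 counts each, Cyp2a5 15 and Cyp2g1 7. Respiratory ciliated cell genes (3 of 5) had a median of 131 CPM, from Foxj1 (101 CPM), Tekt1 (36.7 CPM, 27 counts in cell 3) and Ccdc153, with none of Tmem212. Endothelial and stromal genes (5 of 8) had 18 counts over all cells and ensheathing glia genes (4 of 8) had 14. Pecam1 had 3 of these counts, S100b 2 and Fabp7 2, and Cldn5, Flt1, Col1a1 and Sox10 none. Immune genes (2 of 8) had 8 counts, 7 of them of Tyrobp and none of Ptprc, C1qa or C1qb. Horizontal basal cell genes (1 of 5) had 4 counts of Icam1, with none of Krt5, Krt14 or Krt15. Neuronal progenitor genes (2 of 6) had 3 counts and none of Neurog1, Neurod1 or Kit. Microvillar cell genes, Trpm5, Ascl3, Cftr and Foxi1 among them, had no count in any cell (0 of 7). For the 12 lists examined, 5 of 72 pairs of list and cell lay above percentile 99 and 5 below percentile 1, where chance gives 1.44 on both sides together for genes that vary independently. The pairs are not separate draws, since each cell enters the mean behind the ratios of the others. The gland list alone lay outside in cells 2, 3, 4 and 6, and the immature list in cells 3 and 4.

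**Figure D3:**
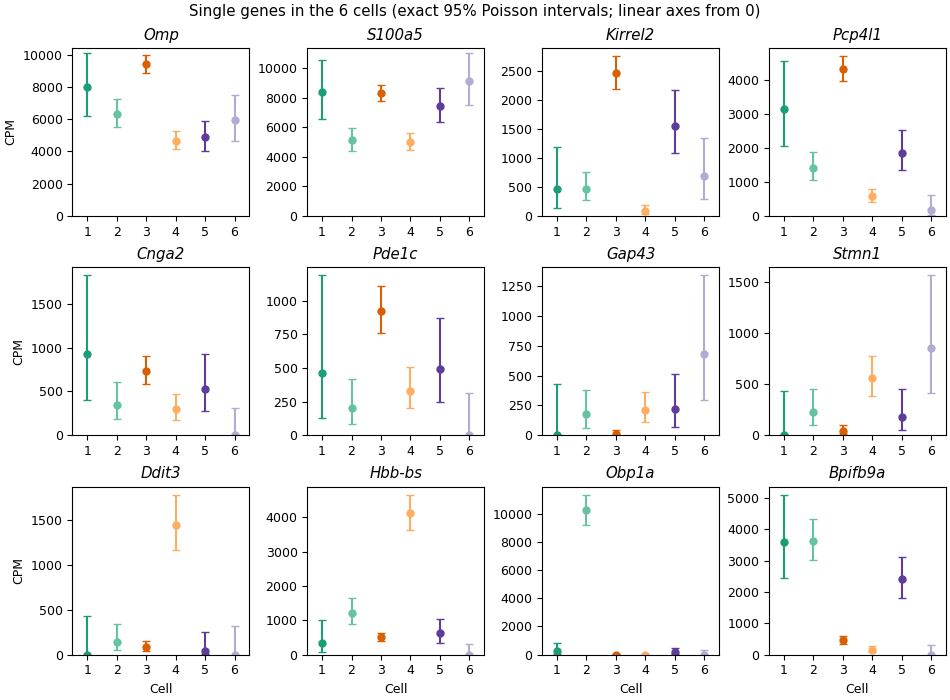
Level (y axis, CPM, linear from 0) of 12 genes in cells 1 to 6 (x axis), with exact 95% Poisson intervals. Omp and S100a5 are high in each cell, Kirrel2 and Pcp4l1 are highest in cell 3, Ddit3 and Hbb-bs in cell 4 and Obp1a in cell 2, and Cnga2 and Pde1c have no count in cell 6.

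S100a5, with a median of 7875 CPM, Omp and Stoml3 were among the most abundant genes. Outside mitochondrial, ribosomal protein and receptor genes, the highest median was that of the noncoding RNA Gm26870 on chromosome 9 (3000282 to 3038313), 9565 CPM. Its level ran from 5174 CPM in cell 3 to 29606 CPM in cell 1. Gm10925, Gm29216 and Gm28661, on chromosome 1 between 24613974 and 24616197, are annotated as pseudogenes and are nuclear copies of mitochondrial sequence, with medians of 8367, 7617 and 7549 CPM. Gm42418, a noncoding RNA that overlaps ribosomal RNA sequence, had a median of 5703 CPM, from 1724 CPM in cell 4 to 21202 CPM in cell 2. Gm43333 had a median of 4550.3 CPM, from 929 CPM in cell 1 to 13284 CPM in cell 4.

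Several genes, chosen for being highest in a single cell, were abundant there. In cell 2, the lipocalin genes of the Obp1 family on chromosome X, Gm14744, Obp1b, 5430402E10Rik and Gm14743, had 462, 426, 460 and 361 counts and at most 8 in any other cell, and Mup4, a major urinary protein gene, had 94 and at most 1. Their coefficients of variation over the 6 cells lay among the 10 highest, with 2.41 for Gm14744. In cell 3, Avp, which encodes vasopressin, had 128 counts (1045 CPM, against 4 counts in cell 4), Ptprn, a protein of secretory granules, 127 (against 2 in cell 5) and Nav1 159. In cell 4, the ubiquitin ligase Rnf185 had 122 counts (2003 CPM), with 32 in cell 3 and 3 in cell 5. In cell 1 the genes were Tsc22d1 (3831 CPM, next highest 1365 CPM in cell 6), Cmip (2554 CPM, next 620.2 CPM in cell 3) and Sgpl1 (1742 CPM, next 666 CPM in cell 5, with overlapping intervals). In cell 5 they were Kcnq1ot1 (932 CPM), an antisense RNA of uncertain strand here, Nrn1l (888 CPM) and Cdkn1a (444 CPM, 10 counts), a cell cycle inhibitor. The intervals of all 3 overlapped that of cell 1, where each had 1 count. In cell 6 the genes were Coch (1962 CPM), Nop53 (1706 CPM) and Zmiz2 (938 CPM, overlapping cell 1), with 23, 20 and 11 counts.

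As whole profiles the neurons were only moderately alike. Spearman's rho across 9760 genes had a median of 0.294 over the 15 pairs of cells (0.160 to 0.438); genes are not independent replicates, and low depth lowers rho. A set of 830 genes had a count in each cell, out of 16483 with a count in any cell, and 346 at equal depth.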

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

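The tests of shared and background reads and of the globin and secretory ratios below were chosen after the results were seen, apart from the comparison of Olfr742 and Olfr741 sequence. Of 111 values examined over the 6 cells, 30 had 1 cell far above the other 5, by more than Dixon's 95% limit for the gap as a share of the range. Chance gives about 1 in 20 for independent, normally distributed values. The CPM here are skewed, depths differ, lists are counted beside their own members, and many genes were named because they were high in a single cell or variable, so the count of such values is no evidence in itself. The limit also ignores counting error. For 21 of the 30 values the exact 95% Poisson interval lay above those of all other cells, and for 9 it overlapped at least 1 of them.

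Cell 2 was apart for secretory transcripts. The gland and secretory list reached 19809.7 CPM, Obp1a 10267 CPM, Obp2a 2581 CPM, Obp1b 12356 CPM, Gm14744 13399.8 CPM, 5430402E10Rik 13342 CPM, Gm14743 10470.4 CPM and Mup4 2726 CPM. Cell 4 was apart for the red blood cell list with 12610.4 CPM, for Hbb-bs with 4121 CPM and for Hbb-bt with 1445 CPM. RNA from other cells of the nose, carried over when the neurons were collected, is a candidate explanation, and both lists were fixed as markers of other cells. A source of constant makeup shared by all cells is argued against, in each case by a single cell. Overlap of intervals between other cells does not show that their ratios are equal. The ratio of alpha-globin to beta-globin counts was 4.88 in cell 3 (3.86 to 6.24), against 1.27 in cell 4 (1.09 to 1.46), 1.88 in cell 2 (1.33 to 2.70) and 2.22 in cell 5 (1.24 to 4.12), where the cell 2 interval overlapped that of cell 4 and the cell 5 interval overlapped those of both cells 3 and 4. The ratio of Obp1a to the sum of Bpifb9a and Bpifb9b was 1.48 in cell 2 (1.25 to 1.75), against 0.0357 in cell 1 (0.00422 to 0.135), 0.0360 in cell 5 (0.00965 to 0.0949) and 0 in cells 3 and 4 (up to 0.0347 and 0.192). A shared source for the other cells, several sources, and expression in the neurons themselves stay open, and no biological explanation was tested.

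Among receptor genes, Olfr1372-ps1 was highest in cell 3 with 620.2 CPM and Olfr482 in cell 4 with 296 CPM. Neither interval lay above those of all other cells. The interval of Olfr1372-ps1 overlapped that of cell 1 alone, where 2 counts gave 28.1 to 839 CPM. The interval of Olfr482 overlapped those of cells 1, 3, 5 and 6. Overlap of intervals does not show that 2 levels are equal. Olfr742 in cells 3 and 4 may hold reads of Olfr741: 12.1% of the 50-base windows in the last 1000 bases of its transcripts occur in Olfr741, and the ratio of Olfr742 to Olfr741 was 0.113 (0.0820 to 0.152) in cell 3 and 0.0829 (0.0465 to 0.138) in cell 4. Sharing in simple proportion to common windows is argued against, since the windows in common with Olfr743 would give 13.0 counts of Olfr742 in cells 5 and 6, where 0 were seen (upper bound 3.69). The windows shared with Olfr741 come within 504 bases of the end of the longest Olfr742 transcript and those shared with Olfr743 within 1073, while in the shortest, of 1120 bases, the order is the other way, 304 against 168. The positions do not settle the matter, and sharing with Olfr741 and expression of Olfr742 both stay open. Olfr1372-ps1 and Olfr1383, the latter named after its value was seen, are not explained by Olfr741 reads, since their ratio in cell 3 would give 55.4 counts in cell 4, where 3 were seen (upper bound 8.77). Reads exchanged between that pair, with 23.8% of the windows of Olfr1372-ps1 in common, stay open. For receptor genes under 10 counts, evenly spread background may account for the counts in cells 3 and 4, where vomeronasal receptor genes had 39.3 and 38.2 counts per exonic megabase against 33.3 and 27.9 for the odorant receptors. It is argued against as the whole cause in cell 2, with 8.87 (5.07 to 14.4) against 30.5 (25.2 to 36.5), and in cell 5, with 1.11 against 8.52, where the intervals also did not overlap. Cells 1 and 6 had too few counts to decide, with 0.554 against 2.84 and 0 against 2.07. All these rates take whole exons, while reads come mainly from 3' ends, and an even spread over genes was not itself tested. No biological explanation was tested.

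The other values are given without explanation. Cell 6 was highest for Gap43 (682 CPM), Vamp2 (1194 CPM), Nop53 (1706 CPM), Coch (1962 CPM) and Zmiz2 (938 CPM). Cell 4 was highest for Kif3a (739 CPM), Rnf185 (2003 CPM) and Ddit3 (1445 CPM). Cell 3 was highest for Tekt1 (220.3 CPM), Nav1 (1297 CPM), Avp (1045 CPM) and Ptprn (1036 CPM). Cell 1 was highest for Cmip (2554 CPM), Tsc22d1 (3831 CPM) and Sgpl1 (1742 CPM), and cell 5 for Kcnq1ot1 (932 CPM) and Nrn1l (888 CPM). The intervals of Gap43, Vamp2, Zmiz2, Tekt1, Sgpl1, Kcnq1ot1 and Nrn1l overlapped that of at least 1 other cell.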

How the results depend on the processing

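The leading receptor of each cell was the same in 6 of 6 cells after thinning to the shallowest cell. The number of dominated cells, 0 at a limit of 90%, was 6 at 50%, 0.05 on average over 20 thinned draws, and 2 with receptor genes of at least 3 counts only, where the median leading share was 81.9% and the 2 cells were the shallowest. The last setting was chosen after the data were seen. Genes per cell fell to a median of 2292.5 at 3 counts, 360.5 at 10 counts and 3610.3 after thinning. Genes found in all cells numbered 221 at 3 counts, 346 after thinning, 3142 with the cells under 20000 counts left out (chosen after the data were seen), and 836 to 1603 with each cell left out in turn. These counts follow from the stricter limit, the lower depth or the fewer cells. List levels moved by less than 1 SD over cells in 251 of 253 values under other scalings and with cells left out, but that SD is large for low or uneven lists. With 1 cell left out, the median moved by over 1.5 times for 7 lists: that of gland and secretory markers, 3089 CPM over all cells, became 1028 or 5149.8 CPM, and those of glia and of endothelial and stromal markers, 28.6 CPM each, became 0 or 57.1 CPM. The values that moved by more than 1 SD were presynaptic genes, at 2985 CPM without mitochondrial, ribosomal protein and receptor genes, and endothelial and stromal markers, at 86.0 CPM without the cells under 20000 counts. The cause was not tested. The median log2 ratio of the gland list in cell 6 was -9.99 with a pseudocount of 1 CPM, because 5 of the 6 genes past the filter had no count there, and -4.43 with 50 CPM. None of the log2 ratios named in the report changed sign under another pseudocount or without the filter on low values, but the sizes of the gland list and of the immature list in cell 3 moved by over 1.5 times. No paired analysis was possible because the cells form 1 group. Depth limits cells 1 and 6 most: there 3 counts are worth 348 and 256 CPM, so genes below those levels were not reliably detectable there.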

Other observations

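The test of pseudogenes and the comparison of splits below were chosen after the pattern was seen, and the genes in this part were named after their values were seen unless the report names them. The balance of the most abundant neuronal transcripts differed between cells. Omp counts exceeded Gfy counts in cells 1 to 5, by a ratio of 1.33 (95% interval 1.11 to 1.59) in cell 4 to 2.96 (2.26 to 3.91) in cell 2. In cell 6 Gfy exceeded Omp, with a ratio of Omp to Gfy of 0.619 (0.453 to 0.842). Pcdh10, a protocadherin of the axon guidance list, had 1598 CPM in cell 5 and 597 CPM in cell 6, 106 CPM in cell 3 and no count in cells 1, 2 and 4. Crmp1, of the immature list, had 853 CPM in cell 6, 115 CPM in cell 4, 44.4 CPM in cell 5 and no count elsewhere.

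Across the 10 ways to divide the 6 cells into 3 and 3, the division of cells 1, 2 and 5 from cells 3, 4 and 6 separated 36 genes by at least 1 log2 unit between the lowest cell of one side and the highest of the other, and the next division 17. With 10 divisions no share under 0.05 is possible. The genes had a mean of at least 100 CPM, and CPM with a pseudocount of 50 CPM were compared. Higher in cells 1, 2 and 5 were 15 genes, among them Malat1 (17, 119 and 139 counts, against 92, 13 and 5 in cells 3, 4 and 6), Bpifb9a, Bpifb9b, Obp1a and Obp1b. In CPM, Malat1 was lower in cell 3 than in cell 1, since cell 3 is far deeper. Counting error was not considered: Obp1a had 2 counts in cell 1, and its 0 in cell 6 allows up to 315 CPM. A 0 in cell 1 allows up to 428 CPM. Higher in cells 3, 4 and 6 were 21 genes, among them Lipe (161, 116 and 18 counts, against 0, 1 and 1 in cells 1, 2 and 5), Ppp2r3a (133, 37 and 15, against 0, 3 and 0) and Gm43333. The division does not follow the leading receptor, since cells 5 and 6 both carry Olfr743.

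Depth as the cause is argued against, because the division of the 3 shallowest from the 3 deepest cells separated 9 genes. A library batch that the labels do not give, with reads placed differently on pseudogenes, is a candidate explanation: 12 of the 21 genes higher in cells 3, 4 and 6 are pseudogenes, where random draws from the 1919 genes examined, 307 of them pseudogenes, gave 3.36 on average and 7 at the upper end of their central 95%. The other genes, such as Lipe, are not accounted for by that test. The draws also treat genes as independent, while pseudogenes with near-identical copies may share reads and vary together. No biological explanation was tested, since the labels give the cells a single group.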
